A study of Homo sapiens with 4 samples.

How the data were processed

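Total RNA of THP1 cells, a human acute monocytic leukemia line, was measured on 4 Affymetrix expression arrays that carry 54675 probe sets. A probe set is a group of short probes read together for part of a transcript, and a gene can have several. Cells had been sorted by flow cytometry with an antibody against the surface receptor IL17RC, giving 2 IL17RC+ and 2 IL17RC− samples per the labels. One label field gives IL-17A at 100 ng/ml for the IL17RC+ samples alone, while the treatment text of all 4 samples describes IL-17A before the sort. Whether the stimulation differed between the groups therefore stays open, and sort and stimulation may go together in every value given. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

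The deposited table holds 1 linear intensity per probe set and array, made by the authors with RMA per the submitters' processing notes. RMA corrects the background, makes the distributions of the arrays equal and combines the probes of a probe set on the log2 scale. Its version is not given in the sources used here, nor is the step that returned its log2 values to linear ones. All deposited values are whole numbers, the lowest is 4 on each array, and dim values therefore move in coarse steps. Medians of the 4 arrays were 58 and 58 in IL17RC− and 59 and 60 in IL17RC+. The number of arrays, 2 per group, limits the precision of every value.

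Values were turned to log2 with no floor and no further normalization. The 62 control probe sets were left out of the tests, which leaves 54613. Control probe sets of 1 further human transcript are not reported here. A table of the platform's annotation gave 1 gene symbol for 41091 of these, several for 1801 and none for 11721, and probe sets with several symbols name no gene here. Entrez identifiers of 41037 probe sets were matched to the RefSeq gene table of the assembly GRCh38.p14, 54 were not, and 0 symbols had to be updated. The table was used for names alone, and the positions of probes and genes are not used here. A gene stands for its probe set with the highest mean over all 4 arrays, which gives 19775 genes. With no detection calls, a probe set is called detected where a group's mean log2 value is at least 6. As a guide to dim values, the 27 Bacillus control probe sets lay between 6 and 51, with a median of 13.

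The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no replicate block, IL17RC+ minus IL17RC−), with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. All adjusted p-values of single genes come from limma. Adjusted values of gene lists come from limma's camera, adjusted over the 32 lists. An exact two-sided test of 2 against 2 cannot give a p under 0.333 and was not run. Values are given as the mean intensity ± SD (n = 2 arrays per group), and fold changes as log2 of IL17RC+ over IL17RC−.

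Before the data were examined, 32 gene lists were fixed: IL-17 receptors and signalling, IL-17A response genes, chemokines, chemokine receptors, cytokines, NF-kB targets, interferon response, pattern recognition, monocyte markers, macrophage differentiation, granule genes, dendritic cell markers, Fc receptors, S phase, G2 and M phase, p53 targets, unfolded protein response, heat shock, immediate early genes, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, cholesterol synthesis, antioxidant targets, complement and coagulation, angiogenesis and matrix remodelling, and markers of T and NK cells, B cells, erythroid cells and platelets, neutrophils, epithelium, and fibroblasts and endothelium. They hold 636 distinct genes, of which 575 were measured. Lists were tested with camera at a preset correlation of 0.01, which compares a list with all other genes. Camera with an estimated correlation and the rotation test fry were alternatives. Fry asks whether the members of a list move on balance in one direction, or in either direction, without reference to other genes.

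Named genes followed a rule fixed before the data were examined. They are IL17RC and IL17RA, the 12 largest rises and 12 largest falls among genes past the test with a mean log2 value of at least 6 in the higher group and both arrays of one group beyond both of the other, and up to 4 members of each list by unadjusted p. Uncharacterised loci were skipped among the largest changes.

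Alternatives were the replicate number as a block, a second quantile normalization, centring each array on its median, only the probe sets with a mean above the median, eBayes with an intensity trend, the mean of a gene's probe sets, 1 probe set per gene, each other IL17RC probe set, an adjusted p under 0.1, limma's treat against a fold of 1.2, and leaving out each array in turn. A pair of further alternatives was chosen after seeing the data: the probe set with the highest mean in IL17RC− as the gene's value, and counting only genes with at least 2 detected probe sets that all passed in the same direction.

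The same code was tested on simulated data built on these arrays, with 54613 probe sets. With 50 probe sets changed at each of 4 sizes, limma recovered 0% at a log2 change of 0.5, 0% at 1, 20% at 2 and 58% at 4, with 0 unchanged probe sets called. With a broad change of 1 log2 unit in 7856 probe sets, it recovered 78.4%, and 4.44% of its calls were false. The simulated noise was independent between probe sets and of equal spread in both groups, so these shares need not hold for the real arrays. A simulated shift of 1 list, chemokines, was found by camera, which also called 1 of the other lists. Chemokines share members such as CXCL8 and CCL2 with the IL-17A response genes, so the other call is not necessarily false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.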

Results

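The data compare THP1 cells that carried the IL-17 receptor subunit IL17RC on their surface with cells sorted as lacking it, with 2 arrays in each group. THP1 is an established monocytic leukemia line used as a model of human monocytes. IL17RC pairs with IL17RA to form the receptor for IL-17A, the cytokine named in the labels. Log2 values of the arrays correlated at 0.996 within IL17RC+ and 0.99 within IL17RC−, and at 0.939 to 0.956 between the groups. Over the detected probe sets, the difference between replicates had an SD of 0.19 log2 units in IL17RC+ and 0.38 in IL17RC−.

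The first question was whether the mRNA of the sorted receptor followed the sort. IL17RC lay at 157.5 ± 13.4 in IL17RC+ cells and 122.5 ± 4.95 in IL17RC− cells, a log2 difference of 0.36 (SE 0.094, 95% interval 0.080 to 0.64) that did not pass limma's test (adjusted p = 0.0708). Its other probe sets gave 0.52 (adjusted p = 0.0879), −0.22 (adjusted p = 0.160) and 0.00 (adjusted p = 1). The sort was on surface protein, which these arrays do not measure. IL17RA, the partner subunit, was 4372 ± 48.1 in IL17RC+ and 5731 ± 146 in IL17RC− by its brightest probe set, which fell by 0.39 (adjusted p = 0.0273). A pair of further IL17RA probe sets rose by 1.26 (adjusted p = 0.0495) and 0.55 (adjusted p = 0.0194), and another lay at −0.28 (adjusted p = 0.110). IL17RA therefore has no single direction on these arrays, and its mean over probe sets was 0.29.

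The next question was which genes differed between IL17RC+ and IL17RC− cells. The largest rises in IL17RC+ were UBE2S, a ubiquitin-conjugating enzyme of mitosis (2620 ± 137 against 43 ± 2.83, log2 5.93), CYBA, a subunit of the phagocyte NADPH oxidase (12380 ± 82.7 against 331 ± 70.7, log2 5.24), the linker histone H1-10 (5.21) and CORO1A, an actin-binding protein of leukocytes (5.16). MPDU1 (4.98), the mitochondrial ribosomal protein MRPL12 (4.92), the proteasome ATPase PSMC3 (4.78), fatty acid synthase FASN (4.52), the granule protease PRTN3 (4.32), the G protein subunit GNAI2 (4.23), thymidine phosphorylase TYMP (4.08) and the ATP-gated channel P2RX4 (4.06) completed the 12. The largest falls were smaller. They were the zinc finger gene ZNF75D (73.5 ± 4.95 against 296 ± 42.4, log2 −2.0), the noncoding BAIAP2-DT (−1.93), ZNF256 (−1.89), WWC3 (−1.88), PTGS2, the inducible cyclooxygenase (19.5 ± 2.12 against 69.5 ± 3.54, log2 −1.84), ZNF232-AS1 (−1.83), ZNF318 (−1.79), GPR146 (−1.77), the sphingosine-1-phosphate receptor S1PR3 (−1.77), PRXL2B (−1.75), the mitochondrial leucyl-tRNA synthetase LARS2 (−1.74) and the iron exporter SLC40A1 (−1.73). Adjusted p-values ran from 0.00642 to 0.0149 for these rises and from 0.00772 to 0.0157 for these falls. Control transcripts had also lost 5' signal in IL17RC−, as given below, so these changes are not necessarily differences between the sorted cells. Some of the lower means lay within the range of the Bacillus controls (6 to 51), so that these folds and their ranks are uncertain. Taken against 51, the log2 fold would be at least 5.68 for UBE2S, 4.06 for MPDU1 and 4.06 for P2RX4, and among the falls −0.45 for PTGS2, −0.54 for SLC40A1, −1.37 for ZNF256 and −1.49 for GPR146.

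In all, 16322 of 54613 probe sets changed (29.9%), of which 5694 were higher and 10628 lower in IL17RC+. By the brightest probe set of each gene, with p-values still adjusted over all probe sets, 6840 of 19775 genes changed, 1209 higher and 5631 lower. Rises were fewer but larger: 2989 called probe sets rose over 2-fold and 119 over 16-fold, while 2476 fell over 2-fold, 7 over 4-fold and 0 over 16-fold. In these counts the loss of 5' signal in IL17RC−, described below, cannot be told apart from a difference between the cells. With any 1 of the 4 arrays left out, limma called 0 probe sets, with 17050 to 21678 at an unadjusted p under 0.05. Limma uses 1 spread per probe set for both groups, although the replicates of IL17RC− differed more than those of IL17RC+.

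Control probe sets that read the 5' end of a transcript separated the groups as well. The 5' probe set of GAPDH read 17388 ± 414 in IL17RC+ and 78 ± 4.24 in IL17RC−, while its 3' probe set read 18416 ± 467 and 16482 ± 541. For beta-actin, the 5' probe set read 28611 ± 543 and 134 ± 5.66 and the 3' one 27688 ± 144 and 27434 ± 2.12. The ratio of 3' to 5' signal was 0.97 in IL17RC+ and 205 in IL17RC− for beta-actin, and 1.06 and 211 for GAPDH. The 18 hybridisation spikes, which are added after the RNA is labelled, differed by a median log2 value of −0.16.

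**Figure D1:**
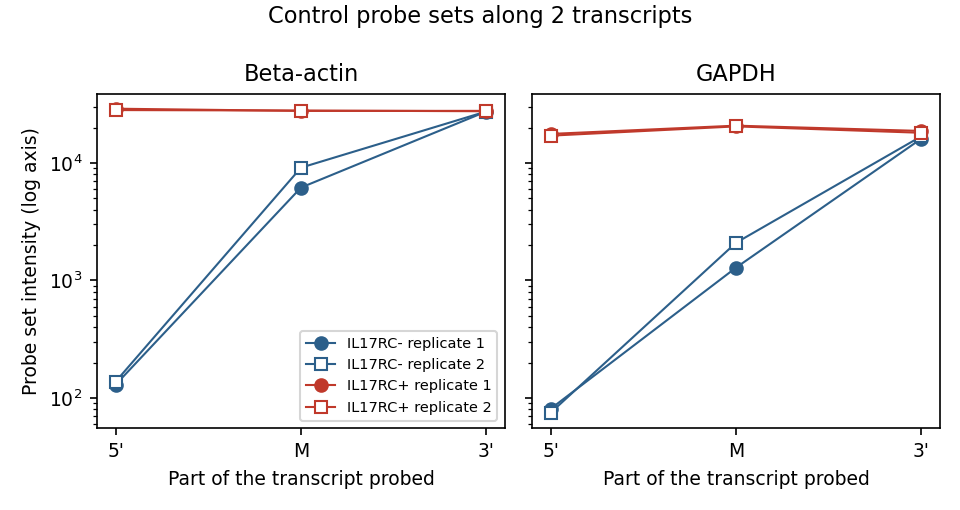
Intensity (log axis) of the control probe sets from the 5' to the 3' part of 2 transcripts, with 1 line per array, IL17RC+ in red and IL17RC− in blue, replicate 1 filled and replicate 2 open. The groups lie together at the 3' end (GAPDH 18416 and 16482) and apart at the 5' end (17388 and 78).

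Probe sets of 1 gene often went different ways. Of 6160 genes with at least 2 detected probe sets, all probe sets rose in 145, all fell in 611, and 1116 had both a rise and a fall. Of the 2269 genes with at least 1 rise, 49.2% also had a fall. Among the largest rises, 7 of the 12 genes had 1 detected probe set, and the probe sets passed together in CYBA (1.04 and 5.24) and TYMP (1.98 and 4.08). The other probe set of MPDU1 fell by 0.61, and those of FASN and MRPL12 read −0.41 and 0.31, neither past the test. Among the largest falls, LARS2, WWC3, ZNF318 and ZNF232-AS1 fell by each of their 2 detected probe sets, while BAIAP2-DT had 2 that rose and 2 that fell and ZNF75D another at 0.10.

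**Figure D2:**
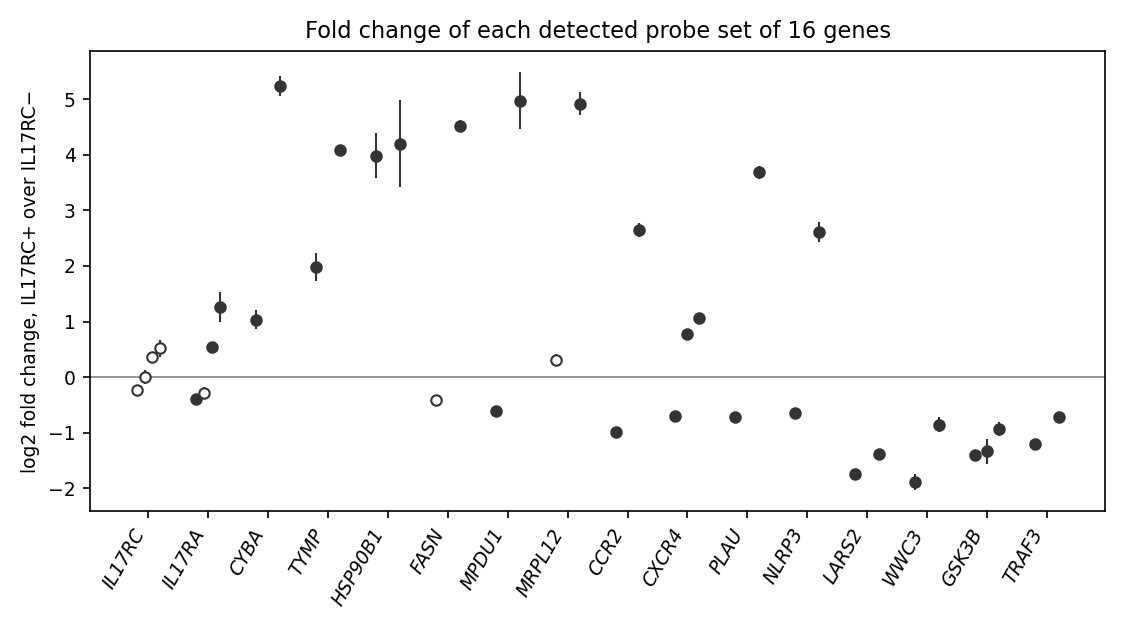
Log2 fold change (IL17RC+ over IL17RC−) of each detected probe set of 16 genes, with bars of 1 standard error and filled points where the adjusted p was under 0.05. Probe sets of CCR2 lie at −0.99 and 2.65 and those of MPDU1 at −0.61 and 4.98, whereas all 3 of GSK3B lie below 0.

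By their brightest probe sets, the genes of IL-17 signalling that changed were lower, but several had other probe sets that rose. Of 19 measured IL-17 receptors and signalling genes, 0 rose and 11 fell (1 and 12 adjusted over the list alone), among them the adaptor TRAF3 (300.5 ± 26.2 against 695 ± 43.8, log2 −1.21), the kinase GSK3B (341 ± 46.7 against 647 ± 28.3, log2 −0.93) and the ubiquitin ligase TRAF6 (−0.58). All detected probe sets of TRAF3, GSK3B and TRAF6 fell, but IKBKB (−0.69) had another at 2.19. Of the 12 members with at least 2 detected probe sets, 5 had both a rise and a fall. Of 27 genes known to respond to IL-17A, 0 rose and 8 fell (0 and 8 adjusted over the list alone), including PTGS2, the monocyte chemoattractant CCL2 (58 ± 4.24 against 151.5 ± 16.3, log2 −1.38) and the calprotectin subunit S100A8 (2695.5 ± 4.95 against 5570 ± 472, log2 −1.04). For 2 of these 8 falls, MMP1 among them, and for 1 of the 11 in signalling, both group means lay within the range of the Bacillus controls. Over all 19775 genes 5631 fell and 1209 rose, a share of falls near that of the response list. Camera gave adjusted p = 0.251 for the signalling list and 0.543 for the response list.

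Among inflammatory genes of monocytes more fell than rose, as over all genes (5631 lower and 1209 higher of 19775). Of 25 chemokines 0 rose and 5 fell (0 and 2 adjusted over the list alone), with CCL23 at −1.01 by its brightest probe set and −1.30 by the other, and CXCL8 at −1.10 beside a probe set that rose by 0.52. Of 13 chemokine receptors 0 rose and 6 fell (0 and 6 adjusted over the list alone). The fractalkine receptor CX3CR1 (325 ± 11.3 against 745 ± 22.6, log2 −1.20) and CXCR2 (−0.84) had 1 detected probe set. CCR2 (−0.99) had another that rose by 2.65, and CXCR4 (−0.69) had 2 others that rose, by 0.78 and 1.07. Of 22 cytokines 1 rose and 4 fell (1 and 4 adjusted over the list alone): TGFB1 rose by 2.84 by 1 of its 2 detected probe sets, the other reading 0.07, and TNF (796 ± 18.4 against 2296.5 ± 333, log2 −1.52) and IL18 (−0.74) fell. Of 21 genes of pattern recognition 1 rose and 10 fell (2 and 11 adjusted over the list alone), among them the muramyl dipeptide sensor NOD2 (156.5 ± 0.71 against 451 ± 28.3, log2 −1.53), NLRC4 (−1.10) and CASP4 (−0.98, and −0.49 by its other probe set). NLRP3 (−0.64) had another probe set at 2.61. Of 18 NF-kB targets 3 rose and 6 fell (3 and 10 adjusted over the list alone), with NFKB2 at 1.28 (another probe set −0.13), IRAK2 at −0.90 and CD83 at −0.45. Among the calls in chemokines and in chemokine receptors, 1 each had both group means within the control range. Members with both a rise and a fall numbered 1 of 3 with several detected probe sets for chemokines, 2 of 4 for chemokine receptors, 0 of 6 for cytokines, 2 of 7 for pattern recognition and 1 of 7 for NF-kB targets. Adjusted p-values by camera were 0.614, 0.251, 0.809, 0.437 and 0.833 in the same order.

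Complement and coagulation had the lowest median of the 32 lists (log2 −0.55). Of 21 genes 0 rose and 12 fell (0 and 15 adjusted over the list alone), including the clotting factor subunit F13A1 (161.5 ± 16.3 against 417.5 ± 41.7, log2 −1.37), complement C5 (−1.11) and thrombomodulin THBD (1736.5 ± 12 against 3552 ± 77.8, log2 −1.03). PLAU (−0.72) had another probe set at 3.68, 2 of the 6 members with several detected probe sets had both a rise and a fall, and 2 of the 12 falls had both group means within the control range. Immediate early genes, which respond within minutes to stimulation or handling, had the highest median (0.18). Of 20 members 8 rose and 5 fell (8 and 7 adjusted over the list alone), with JUN (2727.5 ± 148 against 1512.5 ± 50.2, log2 0.85, its probe sets from 0.012 to 2.21) and FOSB (0.89) among the rises and DUSP2 (−1.23) and EGR1 (1545 ± 2.83 against 2697.5 ± 112, log2 −0.80, with another probe set at 1.04) among the falls. Of 28 interferon response genes 8 rose and 5 fell (8 and 8 adjusted over the list alone), with a median of 0.056. IFI6 rose from 4894 ± 293 to 11728 ± 128 (log2 1.26), OAS2 rose by 0.75 beside a probe set that fell by 1.15, and GBP2 (−1.10) and RIGI (−0.87, with another probe set that rose by 0.70) fell. Of members with several detected probe sets, 0 of 10 immediate early genes and 2 of 13 interferon response genes had both a rise and a fall. These 3 lists had the lowest adjusted p of camera, 0.0616 each, which does not pass.

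Markers of myeloid identity went both ways. Of 14 genes of granules and progenitors 4 rose and 2 fell (4 and 3 adjusted over the list alone), with a mean log2 of 0.68 but a median of 0.0043. The granule proteins AZU1 (10124 ± 449 against 813.5 ± 61.5, log2 3.64) and PRTN3 and the transcription factor CEBPA (4320.5 ± 82.7 against 516.5 ± 23.3, log2 3.06) rose, each by a single detected probe set, and RNASE2 fell by 0.83. Of 15 monocyte markers 2 rose and 4 fell (2 and 4 adjusted over the list alone): the integrin subunit ITGB2 (1.22, with other probe sets at 5.32 and 0.72) and CSF1R (0.77) rose, and ITGAM (−1.12) fell. Of 19 genes of macrophage differentiation 3 rose and 4 fell (3 and 4 adjusted over the list alone), with the protease CTSD at 2.12, SPP1 at 1.04, CD36 at −0.90, and LPL at −0.51 beside a probe set at 2.94. Of 20 dendritic cell and MHC class II genes 2 rose and 4 fell (3 and 5 adjusted over the list alone). FSCN1 read 1.21 (another probe set 0.18), IRF8 0.78, HLA-DPA1 −1.29 and CD74 −0.60 (another probe set −0.020). Of 11 Fc receptors 2 rose and 2 fell (2 and 2 adjusted over the list alone), with FCGRT at 0.77 and FCGR2A at −0.69. For 1 of the 6 calls among dendritic cell genes both group means lay within the control range. Members with both a rise and a fall were 0 of 2, 1 of 7, 2 of 4, 1 of 5 and 0 of 3 with several detected probe sets. Adjusted p-values by camera were 0.102, 0.361, 0.545, 0.441 and 0.361.

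Genes of the cell cycle and stress also split. Of 19 S phase genes 3 rose and 4 fell (3 and 7 adjusted over the list alone), with MCM4 at 1.51 (its probe sets from −0.070 to 4.46) and GINS2 at −0.77 (another probe set 0.21). Of 24 genes of G2 and M phase 2 rose and 8 fell (2 and 9 adjusted over the list alone): the kinase PLK1 rose from 90 ± 2.83 to 454.5 ± 0.71 (log2 2.34), and AURKA (−1.01, with another probe set at −0.071) and CENPF (−0.93) fell. Of 17 p53 targets 3 rose and 6 fell (3 and 6 adjusted over the list alone). The apoptosis effector BAX was up by both detected probe sets (1.87 and 1.82). TNFRSF10B read −0.85, with 3 detected probe sets from −0.85 to −0.093, of which 1 passed. Of 20 genes of the unfolded protein response 3 rose and 5 fell (3 and 5 adjusted over the list alone): the chaperone HSP90B1 (1266 ± 109 against 85 ± 41, log2 3.98) and the phosphatase subunit PPP1R15A (2.43) rose by both detected probe sets, HSPA5 read 1.34 and −1.35 by its 2, and DDIT3 fell by 0.92. Of 11 heat shock genes 1 rose and 2 fell (2 and 2 adjusted over the list alone), with HSPB1 at 0.42 and HSPE1 at −0.44. Members with both a rise and a fall were 1 of 12, 0 of 12, 3 of 9, 4 of 12 and 3 of 7 with several detected probe sets. Adjusted p-values by camera were 0.809, 0.833, 0.548, 0.251 and 0.361.

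Respiratory chain genes fell more often than they rose. Of 30 oxidative phosphorylation genes 3 rose and 17 fell (3 and 21 adjusted over the list alone), including the complex I subunits NDUFA2 (2439 ± 42.4 against 4731 ± 339, log2 −0.95) and NDUFB8 (3806 ± 35.4 against 6423.5 ± 82.7, log2 −0.76), the latter by all 3 of its detected probe sets. NDUFV1 rose by 0.71 (another probe set −0.32), and SDHC (1.72) had 3 probe sets that rose and 2 that fell. Of 27 genes of hypoxia and glycolysis 6 rose and 10 fell (6 and 11 adjusted over the list alone), with DDIT4 at 1.10, ALDOC at 0.98, PFKFB3 at −1.06 and the glucose transporter SLC2A1 at −1.02. In both lists 1 of 13 members with several detected probe sets had both a rise and a fall. Camera gave adjusted p = 0.20 for oxidative phosphorylation and 0.437 for hypoxia and glycolysis.

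Few markers of other cell types changed, and many were not detected. Detected were 11 of 22 T and NK cell, 8 of 13 B cell and 8 of 13 erythroid and platelet markers. So were 8 of 16 neutrophil, 8 of 13 epithelial and 5 of 14 fibroblast and endothelial markers. Of 22 T and NK cell markers 0 rose and 1 fell (0 and 1 adjusted over the list alone), of 13 B cell markers 1 rose and 2 fell (1 and 2), of 13 erythroid and platelet markers 0 rose and 1 fell (0 and 0), of 16 neutrophil markers 0 rose and 2 fell (0 and 2), of 13 epithelial markers 1 rose and 2 fell (0 and 1), and of 14 fibroblast and endothelial markers 0 rose and 1 fell (0 and 1), with the counts in brackets adjusted over the list alone. Those that fell include IL7R (94 ± 9.9 against 213.5 ± 13.4, log2 −1.19, with another probe set at 0.92), S100P (−0.93), MITF (−1.07, with another probe set at 0.61) and PECAM1 (2709.5 ± 118 against 6131.5 ± 6.36, log2 −1.18, beside 2 probe sets that rose). The rise among B cell markers (CR2, 16.5 against 11), the fall among erythroid and platelet markers (TUBB1, 22 against 32) and 1 fall among epithelial markers (RPE65, 5.5 against 8.5) had both group means no higher than the Bacillus controls. Members with both a rise and a fall were 1 of 4, 1 of 2, 0 of 3, 0 of 1, 1 of 3 and 1 of 2 with several detected probe sets. Adjusted p-values by camera were 0.208, 0.437, 0.251, 0.361, 0.437 and 0.466.

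Over all 32 lists, camera called 0, with 6 at an unadjusted p under 0.05. With an estimated correlation it also called 0, and the lowest value was adjusted p = 0.696 with an estimated correlation. Fry called 4 lists as moving on balance in one direction (adjusted p = 0.0129 each). They were chemokine receptors (mean log2 −0.44), pattern recognition (−0.36), granule genes (0.68) and oxidative phosphorylation (−0.31). It called all 32 as changing in either direction. Since fry makes no reference to other genes and 29.9% of all probe sets changed, these calls do not set the lists apart. The median gene lay at log2 −0.20, and camera placed 16 lists with a median below 0 above the other genes. Median and mean differed in sign for 3 lists: ribosomal proteins, neutrophil markers and epithelial markers. Medians also turned sign with the setting. With the mean of a gene's probe sets those of S phase genes (−0.31 to 0.15), monocyte markers (−0.17 to 0.13) and heat shock genes (−0.083 to 0.42) went above 0, and among the brighter probe sets so did that of fibroblast and endothelial markers (−0.068 to 0.18). Centring the arrays on their medians took those of granule genes (−0.032), the unfolded protein response (−0.011), neutrophil markers (−0.013) and epithelial markers (−0.014) below 0, and other medians near 0 turned with an array left out.

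**Figure D3:**
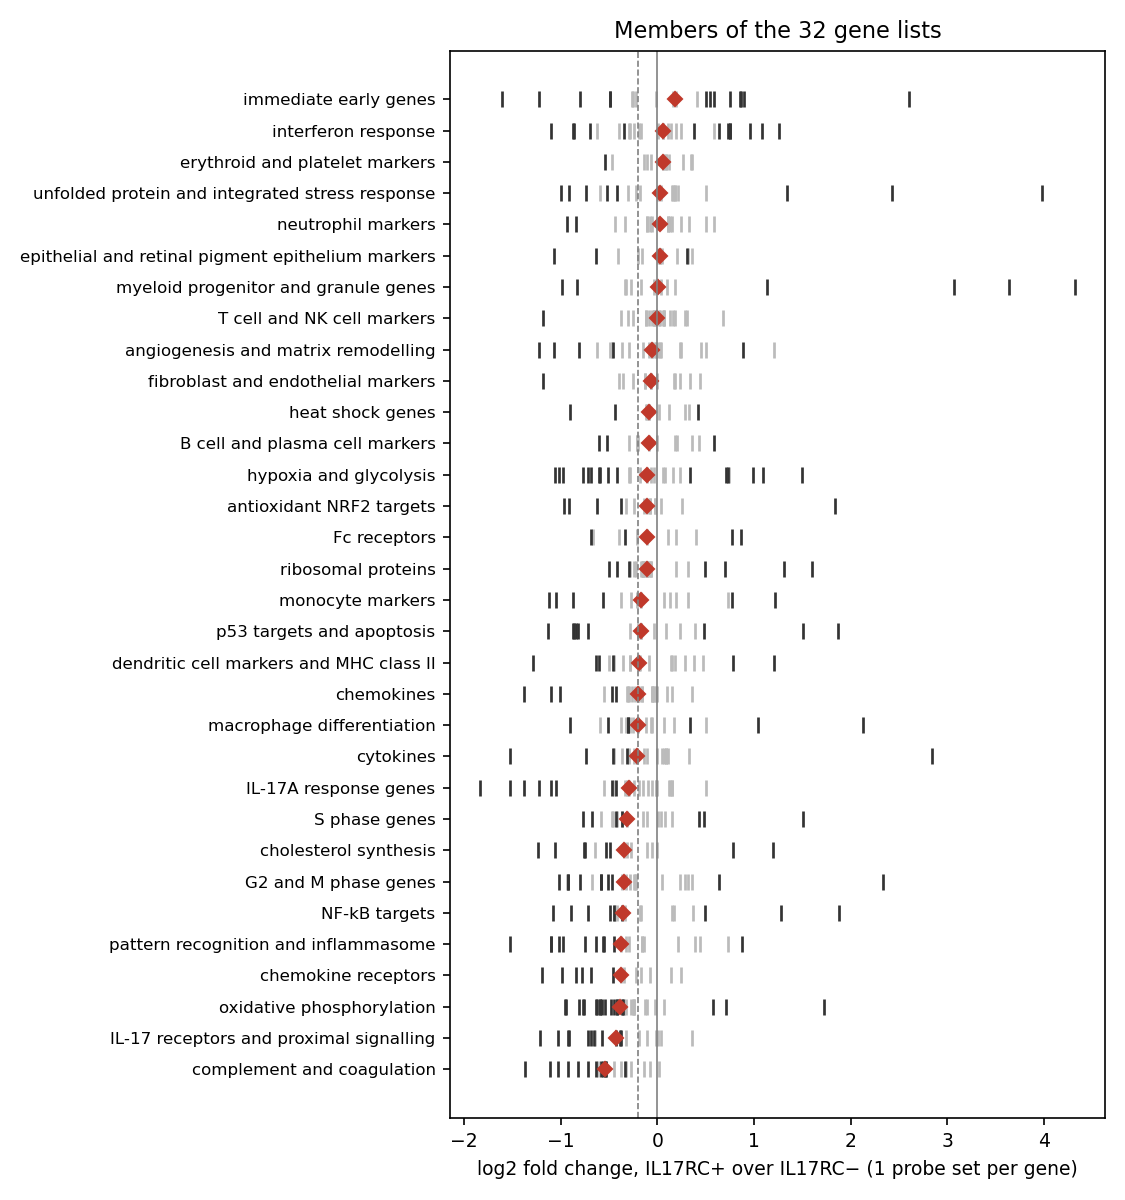
Log2 fold change (IL17RC+ over IL17RC−) of each measured member of the 32 gene lists, 1 tick per gene, dark where the adjusted p was under 0.05, with the list's median as a red diamond and the median of all genes (−0.20) as a dashed line. Medians run from −0.55 for complement and coagulation to 0.18 for immediate early genes.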

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

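The tests on control probe sets, on rises and falls within a gene, on the order of probe sets and on other splits of the arrays were chosen only after the result was seen, and so were the conditions in the list tests on the members' spread and on called members left out.

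Control probe sets outside the comparison differed between the groups. The 5' probe sets were higher in IL17RC+ by 7.74 for beta-actin and 7.80 for GAPDH on the log2 scale. For 18S ribosomal RNA the 5', middle and 3' probe sets were all higher, by 3.76, 3.16 and 3.23, and for 28S they were higher by 6.46, 1.75 and 0.28. The probe set for Alu repeats was higher by 0.72.

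Control transcripts lost 5' signal in IL17RC−, and within many genes the probe sets went opposite ways. In 123 genes the order of a pair of probe sets turned over by over 1 log2 unit each way on all 4 arrays. For these genes this argues against a scaling by the authors that keeps the order of probe sets within an array. RMA equalises the arrays before it combines probes, so it need not keep that order, and its scaling is not excluded. A difference in expression level alone is argued against for beta-actin and GAPDH, since it would move both ends of a transcript together, while the gap between 3' and 5' signal was larger in IL17RC− by at least 7.64 log2 units (SD within groups up to 0.126). Shorter labelled transcripts in IL17RC−, from degraded RNA or another labelling, may account for both: within genes the difference between the IL17RC− arrays correlated with the fold change at 0.368 across probe sets, against 0.0743 for the IL17RC+ arrays, although the fold change holds the same arrays. For genes in general a difference of the sorted cells cannot be told apart from it, since both IL17RC− arrays carry the loss, probe positions are not used here, and the 49.2% of genes with a rising probe set that also had a falling one only restates the pattern.

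Immediate early genes had the highest median of the lists, without passing camera. Transcripts shortened in IL17RC− would raise the probe sets far from the 3' end, so the lowest probe set of each gene should look like that of other genes. For the 10 of 20 members with at least 2 detected probe sets, the median of the lowest log2 fold changes was 0.099, at percentile 100 of 10000 random lists (their median −0.67), past the bound set in advance at the highest 2.5% (−0.31), and a 95% bootstrap interval over members was −0.16 to 0.41. The value does not exclude shortened transcripts, because the list was picked out for its high median while the random lists were not, and because 7 of its 13 called members have 1 detected probe set and are left out, among them FOSB (0.89) and DUSP2 (−1.23). Shortened transcripts, a difference between the sorted cells, handling and stimulation all stay open.

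The interferon response list is read in the same way. The 13 of its 28 measured members with at least 2 detected probe sets had a median lowest log2 fold change of −0.24, at percentile 97.8 of random lists, just past the bound set in advance at −0.25. A bootstrap interval over these members, −0.40 to 0.084, holds the bound, and 6 of the 13 called members are left out. Both conditions were added after the percentile was seen, and without them the value would have counted against shortened transcripts for this list, as it would for immediate early genes. Shortened transcripts may therefore still account for this list, and a biological difference stays open as well.

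The 4 arrays can be split into 2 and 2 in 3 ways. The real split changed 16322 probe sets and was the only 1 of the 3 to change as many, with 0 the highest of the others by limma (84 and 127 at an unadjusted p under 0.05), but 3 splits are too few for a share under 0.05.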

How the results depend on the processing

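The alternatives that take the probe set brightest in IL17RC− or only genes with agreeing probe sets were chosen only after the result was seen.

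Counts of changed probe sets stayed within 1.5 times 16322 with a second quantile normalization, centring, only the brighter probe sets, an intensity trend and an adjusted p under 0.1, from 15476 to 22646. They were 9127 against a fold of 1.2, 7946 with 1 probe set per gene fitted and adjusted over genes alone (1437 higher, 6509 lower), 6904 with the mean of a gene's probe sets (1985 and 4919), 8165 with the probe set brightest in IL17RC− (1276 and 6889) and 756 genes with agreeing probe sets (145 and 611). Settings per gene test fewer items; otherwise the cause was not tested. With the replicate number as a block, which leaves fewer residual degrees of freedom, the count was 5999 (2435 and 3564). Of these, 5912 were shared with the fit without the block. Their directions had to be the same, since the block cannot change a fold change in this balanced design. Deviations of same-numbered arrays correlated at −0.027, which gives no sign of a pairing by number but does not exclude one. Leaving out each array gave 0 to 0 changed, higher or lower probe sets by limma with 1 residual degree of freedom, the lone array being assumed to vary like the other group (17050 to 21678 at an unadjusted p under 0.05, lowest adjusted p 0.0615).

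IL17RC passed among the brighter probe sets alone (0.36, adjusted p = 0.0413, over alternatives 0.0413 to 1), where fewer were tested. It did not pass after a second quantile normalization (0.36), after centring (0.32), with the mean of its probe sets (0.16) or with an array left out (0.27 to 0.45), and read −0.22 by another probe set, which is also the brightest in IL17RC−. Camera at the preset correlation called 3 lists after a second quantile normalization, 4 after centring, 3 among the brighter probe sets, 4 with the mean of a gene's probe sets and 3 with the probe set brightest in IL17RC−, against 0 before, with interferon response and immediate early genes among them each time. Complement and coagulation was called as lower after quantile normalization, after centring and by the probe set brightest in IL17RC−, granule genes after centring and among the brighter probe sets, and heat shock (adjusted p = 0.00505) and the unfolded protein response (adjusted p = 0.0458) with the mean of probe sets. With an estimated correlation camera called 0 on the unaltered values (lowest adjusted p = 0.696 with an estimated correlation), and it was not run in the other settings. Fry called 4. Leaving out an array gave 0 to 2, and 2 without IL17RC− replicate 2 or without IL17RC+ replicate 2. The cause was not tested.

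All 132 named genes kept their direction under a second quantile normalization, centring and each array left out. The intensity trend and the block cannot change a fold change in this balanced design, so directions kept under them carry no weight. The largest rises and falls were chosen with both arrays of one group beyond both of the other. Leaving out 1 array therefore could not turn their sign. Of the 131 past the test, 40 lost it with the block, 26 with the mean of a gene's probe sets and all 131 with any array left out. With the mean of probe sets the sign turned for ABCC1 (0.14), BEST1 (−0.083), CCR2 (0.83), CD74 (0.11), CXCR4 (0.39), FEN1 (0.37), HSPA4 (0.82), HSPA5 (−0.0066), IKBKB (0.48), IL17RA (0.29), LPL (1.21), LTB (0.0050), NLRP3 (0.98), PECAM1 (0.080), PLAU (1.48) and RPL18 (−0.21). With the probe set brightest in IL17RC− it turned for FASN (−0.41), MPDU1 (−0.61), NFKB2 (−0.13) and SDHC (−0.068). Whole-number values limit dim genes, whose control background reached 51.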

Other observations

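The lists in this part were fixed in advance, and only the count of genes with agreeing probe sets was chosen after the result was seen.

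Ribosomal protein genes went both ways. Of 26 measured, 4 rose and 3 fell (4 and 2 adjusted over the list alone): RPL8 rose from 6383 ± 409 to 19262 ± 267 (log2 1.59), RPS14 rose by both detected probe sets (1.31 and 1.00), and RPS19 rose by 0.70 beside a probe set that fell by 0.87. Of 15 genes of cholesterol synthesis 2 rose and 6 fell (2 and 9 adjusted over the list alone). MVD read 1.19 and MVK 0.78, the latter with 4 detected probe sets from −0.11 to 0.78, of which 1 passed. NSDHL read −1.23 (another probe set −0.021) and LSS −0.76, which had another probe set that rose by 0.36. Of 15 antioxidant targets 1 rose and 4 fell (2 and 4 adjusted over the list alone), with PGD at 1.84 (another probe set 0.10), TXNRD1 at −0.96 and SRXN1 at −0.62. Of 24 genes of angiogenesis and matrix remodelling 1 rose and 4 fell (1 and 4 adjusted over the list alone), with the membrane protease MMP14 at 0.89 (its probe sets from 0.27 to 2.14) and MMP2 at −1.07, and 3 of these 5 calls had both group means within the range of the Bacillus controls. Members with both a rise and a fall were 3 of 12, 3 of 9, 2 of 9 and 1 of 5 with several detected probe sets. Adjusted p-values by camera were 0.441, 0.441, 0.984 and 0.441.

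Of 6160 genes with at least 2 detected probe sets, all of these passed in the same direction in 756, with 145 up and 611 down. Named genes among those up include CYBA, TYMP, HSP90B1, PPP1R15A, BAX and RPS14, and among those down GSK3B, TRAF3, TRAF6, NDUFB8, CCL23, CASP4, CD36, HLA-DPA1, ITGAM, SLC2A1 and LARS2. Agreement of probe sets does not separate a difference between the cells from the loss of 5' signal, since probe positions are not used here.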
